A study of Homo sapiens with 2 samples.

How the data were processed

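NCI-H889 is an established human small cell lung cancer line. Per the labels, its cells were grown in RPMI medium with 10% fetal calf serum, given a negative control siRNA (si-NC) or an siRNA against BAF53B (si-BAF53B), and harvested after 72 h. BAF53B is the older name of ACTL6B. Total RNA (250 ng) was turned into biotinylated cDNA with a whole-transcript labelling kit and hybridised to expression arrays. There were 2 arrays, 1 per group, and each group was taken from the sample titles.

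The deposited values are log2 expression values per probe set. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, and the Transcriptome Analysis Console, both without a version. The genome build and the annotation version are not given in the sources used here. The table held 21448 probe sets for each array. The si-NC median was 6.40 and the si-BAF53B median 6.40, and the sorted values of the arrays lay at most 0.195 apart. No further normalization was applied in the primary analysis. Quantile-based normalization gives both arrays nearly the same distribution, so a shift shared by most transcripts would not be visible in these values.

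Probe sets were named through the platform annotation: 17709 had 1 gene symbol, 0 had several and 3739 had none there. All 17709 were matched by Entrez ID to RefSeq annotation of GRCh38.p14, which was used for names, gene spans and chromosomes only, and 0 symbols differed. Probe sets of 1 symbol were averaged, which gave 17687 genes, 20 of them with more than 1 probe set. Unnamed probe sets stayed out of the gene comparisons and are described separately.

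With 1 array per group no test between conditions is possible, so no p-value, SD of a group or standard error is given. Each gene has its log2 difference, si-BAF53B minus si-NC. A gene was counted as higher or lower when it differed by at least 2-fold and its mean level was at or above the median of all genes, 6.86 on the log2 scale (the floor). Where members of a list are counted as higher or lower, only the sign of their difference is meant. The spread of the differences was described by level decile with an SD derived from the median absolute deviation. That spread describes differences between these arrays over genes and holds no variation between cultures. The number of arrays limits the precision.

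For 36 gene lists, 30 of stated symbols and 6 by symbol pattern, the median log2 difference of all measured members was set against 10000 random lists of the same size matched on mean level in 20 bins. A list was said to stand apart when its percentile was under 2.5 or over 97.5, which describes these arrays only. Of 800 stated members, 722 were measured. The ribosomal protein list was the least complete, with 18 of 35 members.

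The named genes were chosen by a fixed rule. ACTL6B came first. Next were the 14 genes with the largest positive and the 14 with the largest negative difference among genes at or above the floor, leaving out snoRNA, microRNA, LOC and unnamed open reading frame symbols. From each list, at most 4 members with the largest absolute difference were eligible, among members at or above the floor, or among all members where fewer than 4 were. INSM1, NEUROD1, CHGA, SYP, NCAM1, DLL3, ACTL6A, REST, MYCL, CDKN1A and MKI67 were eligible whatever their difference. NEUROD1 is not analysed here, and 1 further gene of the rule and 1 of the lists are not reported here. Other genes are marked as chosen after their values were seen. The groups, comparisons, lists, naming rule and the alternatives listed next, except those marked as added, were fixed before the data were examined.

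The alternatives were other floors, 1.5-fold and 3-fold thresholds, centring on the median difference, removal of a lowess trend on level (span 0.3), a second quantile normalization, the brightest probe set per gene, list members at or above the floor, means in place of medians, unmatched random lists, and lists without shared members. Removal of a lowess trend on gene span, 50 level bins, and the second quantile normalization of the ACTL6B value were added after the data were seen. The calculation was tested on simulated data for si-BAF53B against si-NC with 17687 genes, of which 100 differed by 3-fold and 100 by 6-fold. It recovered 98% of the 3-fold and 100% of the 6-fold genes and counted 16 unchanged genes. Of 360 unchanged lists, 16 (4.44%) fell outside the limits, and a simulated S phase shift of -0.3 was below the lower limit in 10 of 10 runs. Each gene was drawn independently from a normal distribution, and the simulated shift was larger than the observed S phase median of -0.17. These rates therefore check the calculation only and do not carry over to the measured arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.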

Results

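Gene expression was measured in NCI-H889 cells 72 h after transfection with a negative control siRNA or with an siRNA against ACTL6B (BAF53B), an actin-like subunit of the neuronal form of the BAF chromatin remodelling complex. The comparison asks how expression differs when this subunit is targeted. Each condition was measured on 1 array, so the differences have no replicate check. Values are log2 expression, and differences are si-BAF53B minus si-NC. Across the 17687 genes the arrays correlated at r = 0.994, a value over genes, which are not independent replicates.

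ACTL6B was the gene with the largest drop. Its level was 9.87 in si-NC and 7.27 in si-BAF53B, a log2 difference of -2.59, which left 16.6% of the si-NC level. Of all probe sets, named or not, 0 had a larger drop. Its paralog ACTL6A, the subunit of the non-neuronal BAF complex, stood at 11.37 in si-NC and 11.53 in si-BAF53B.

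Of the 8844 genes at or above the floor, 32 were at least 2-fold higher in si-BAF53B and 26 at least 2-fold lower. The lower genes after ACTL6B were led by the receptor tyrosine phosphatase PTPRG (-1.79), the small GTPase gene RAB19 (-1.64) and ABHD5 (-1.44), a co-activator of triglyceride breakdown. Also among them were the adhesion genes NEGR1 (-1.40) and LRFN5 (-1.32) and AP3B2 (-1.30), a subunit of an adaptor complex. The growth factor gene HDGF (-1.35), the CREB co-activator gene CRTC2 (-1.34), MZT1 (-1.28) of the gamma-tubulin complex, the kinase gene PAK5 (-1.26), S100A13 (-1.26), RCBTB1 (-1.18) and TRMT10C (-1.12), a subunit of mitochondrial RNase P, completed the 14 lowest. On the si-BAF53B array itself RAB19 (6.09), PTPRG (6.18), RCBTB1 (6.64), LRFN5 (6.74) and PAK5 (6.75) were below the floor of 6.86, where differences spread more widely.

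The highest genes were the metalloprotease gene ADAM12 (1.54), the semaphorin receptor gene PLXNC1 (1.45) and SESN3 (1.38), a sestrin. SC5D (1.38), an enzyme of cholesterol synthesis, and LYPLA1 (1.38), an acyl-protein thioesterase, followed. The remaining members of the 14 highest were LIX1L (1.34), ANXA2 (1.33), SH3BGRL (1.31), the centrin gene CETN3 (1.28), the chaperone gene DNAJB6 (1.28), the RNA gene ANKRD13C-DT (1.20), the metallothionein gene MT1X (1.20), the extracellular matrix gene TNR (1.19) and the interferon-inducible gene IFI6 (1.18). On the si-NC array itself ANKRD13C-DT (6.73) and CETN3 (6.77) were below the floor. Measured in spreads of their level decile, LYPLA1 (7.01) and DNAJB6 (6.52) were the furthest apart of these 14, against 7.96 for ACTL6B.

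Most genes at or above the floor, 93.6%, differed by less than 1.5-fold. Normally distributed differences with the spread of each level decile would place 15.35 genes at 2-fold or more, against 58 observed. Below the floor the same calculation gives 85.85 against 186 observed. More genes than the normal number were thus found among dim genes too, and the excess does not tell how many of the 58 changed. The split of 32 higher and 26 lower became 36 and 19 after removal of a trend on level. Below the floor, 119 genes were at least 2-fold higher and 67 lower, and the differences spread more widely there, with an SD from the median absolute deviation of 0.379 against 0.276 at or above it.

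**Figure D1:**
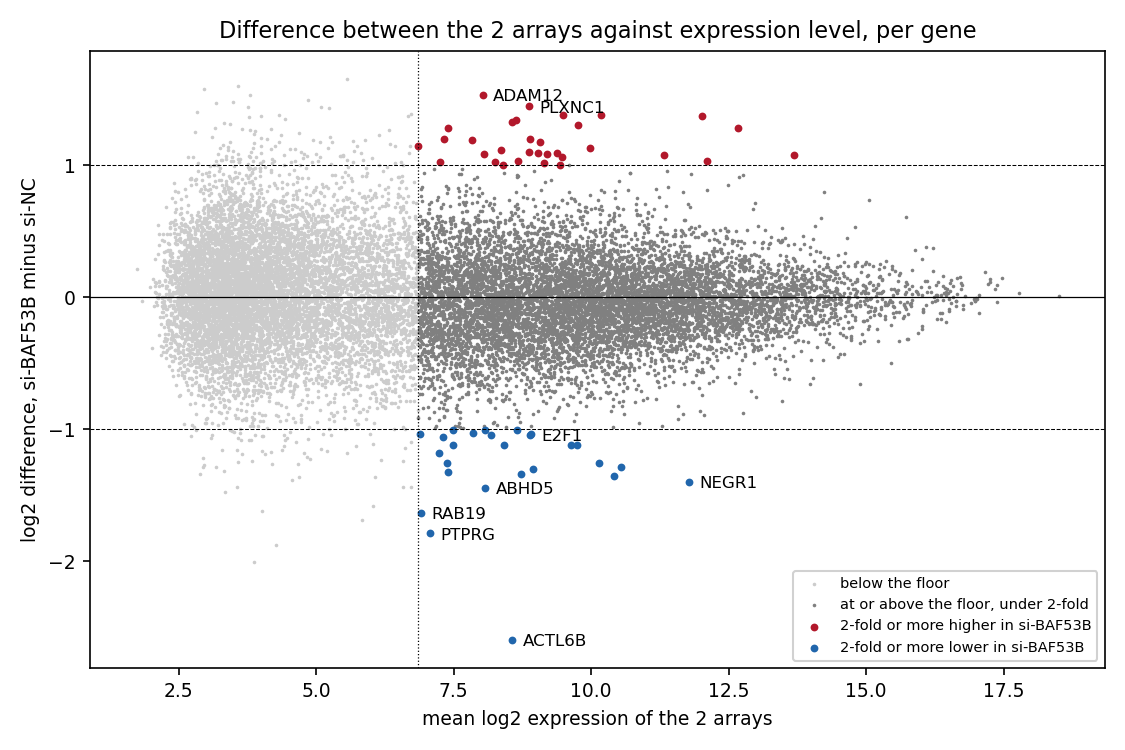
Log2 difference, si-BAF53B minus si-NC, of each of 17687 genes against its mean log2 expression over both arrays. Each point is a gene, the dotted line marks the floor at 6.86 and the dashed lines mark 2-fold; ACTL6B is the lowest point, at -2.59.

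Neuroendocrine marker genes lay close together on both arrays. Of 24 measured, 12 were higher and 12 lower in si-BAF53B, and 0 differed by 1.5-fold or more. The transcription factor gene INSM1 was at 14.37 and 14.41, chromogranin A (CHGA) at 14.80 and 14.81, synaptophysin (SYP) at 9.63 and 9.73, and the adhesion gene NCAM1 at 15.42 and 15.48 in si-NC and si-BAF53B. The members furthest apart were MYT1 (-0.47), RUNDC3A (-0.37), SYN1 (-0.29) and CHGB (-0.26). The list median was -0.04, at percentile 43.3 of random lists.

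Regulators of small cell lung cancer subtypes had a median of -0.12 over 21 genes, 14 of them lower, at percentile 2.59, just inside the limit. They were below it in 5 of 9 alternatives, but at percentile 11.0 without members shared with another list and 8.3 against unmatched random lists. MYCL, a MYC family oncogene, was at -0.61, POU3F2 at -0.26, HES6 at -0.25 and NFIB at -0.22, and 0 members differed by 2-fold. Notch pathway genes had a median of -0.11 (percentile 11.2, 25 genes), which turned to 0.08 (percentile 78.8) without members shared with another list. Of the Notch ligand genes, DLL4 was at -0.47, DLL1 at -0.30, DLL3 at -0.25, JAG1 at 0.51 and JAG2 at 0.56. Each of these was small beside the variation of genes of like level, from 0.87 (DLL3) to 1.57 (JAG2) spreads of its level decile. The neuronal repressor REST was near background, at 2.39 in si-NC and 2.93 in si-BAF53B. Non-neuroendocrine markers (median 0.06, percentile 61.1) and tuft cell markers (0.02, percentile 46.8) did not stand apart. Only 1 of the 24 non-neuroendocrine markers, the annexin gene ANXA1 (0.84), reached the floor.

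Synaptic vesicle and secretory granule genes were slightly higher: 21 of 30 lay above their si-NC level, with a median of 0.10 at percentile 98.2. The granule membrane protein gene PTPRN was at 0.82, the prohormone chaperone gene SCG5 at 0.48, CPE, a prohormone-processing enzyme, at 0.34 and CADPS2, a factor of granule release, at -0.63, and 0 members differed by 2-fold. Without members shared with another list the percentile was 94.5, and against unmatched random lists 92.4. Neuronal structure genes had a median of 0.00 (percentile 54.4), with ELAVL4 at 0.42, NOVA1 at 0.43, CELF4 at -0.72 and the neurofilament gene NEFM at -0.65. Ion channel and receptor genes had a median of -0.03 (percentile 43.9), with KCND3 at 0.33 and CHRNA5 at -0.35. Protocadherin cluster genes had a median of 0.13 (percentile 90.8), with PCDHB11 at 0.88.

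The other BAF subunit genes were slightly higher, 19 of 29, with a median of 0.09 at percentile 98.1. BCL11A (0.62), ARID1B (0.56), SMARCD1 (0.40) and ARID2 (0.30) were the highest at or above the floor, BCL11B, chosen after its value was seen, was at 0.38 below it, and 0 members differed by 2-fold. The list no longer stood apart among members at or above the floor (percentile 97.4), with 50 level bins (97.0) or against unmatched lists (91.6).

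S phase genes were lower in si-BAF53B: 24 of 33 lay below their si-NC level, with a median of -0.17 at percentile 0.22. E2F1, a transcription factor that drives entry into S phase, was at least 2-fold lower (-1.04). The next lowest were MCM6 at -0.66, CDC45 at -0.64 and CDT1 at -0.63, genes of the replicative helicase and its loading. Other helicase genes, chosen after their values were seen, were closer to 0: MCM3 at -0.28, MCM5 at -0.14 and MCM7 at -0.0009. Of the 9 higher members, CCNE1 (0.53) and RRM2 (0.39), also chosen after their values were seen, were the highest. G2 and mitosis genes did not stand apart, with a median of -0.06 (percentile 19.9), although 24 of 35 were lower, a count like that of the S phase list. Among them MKI67 was at -0.04, KIF11 at -0.36, UBE2C at -0.35 and HMMR at 1.12. All genes at or above the floor had a median of -0.04, so a count of lower members does not by itself set a list apart. Replication-dependent histone genes had a median of -0.03 (percentile 37.5, 61 genes), with H2BC13 at -0.66. Among p53 target genes (median -0.09, percentile 16.6) the cell cycle inhibitor CDKN1A was at -0.09, ZMAT3 at 1.09 and AEN at -0.82. Cell death genes had a median of -0.04 (percentile 43.6), with BNIP3L at 0.85 and APAF1 at 0.51.

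**Figure D2:**
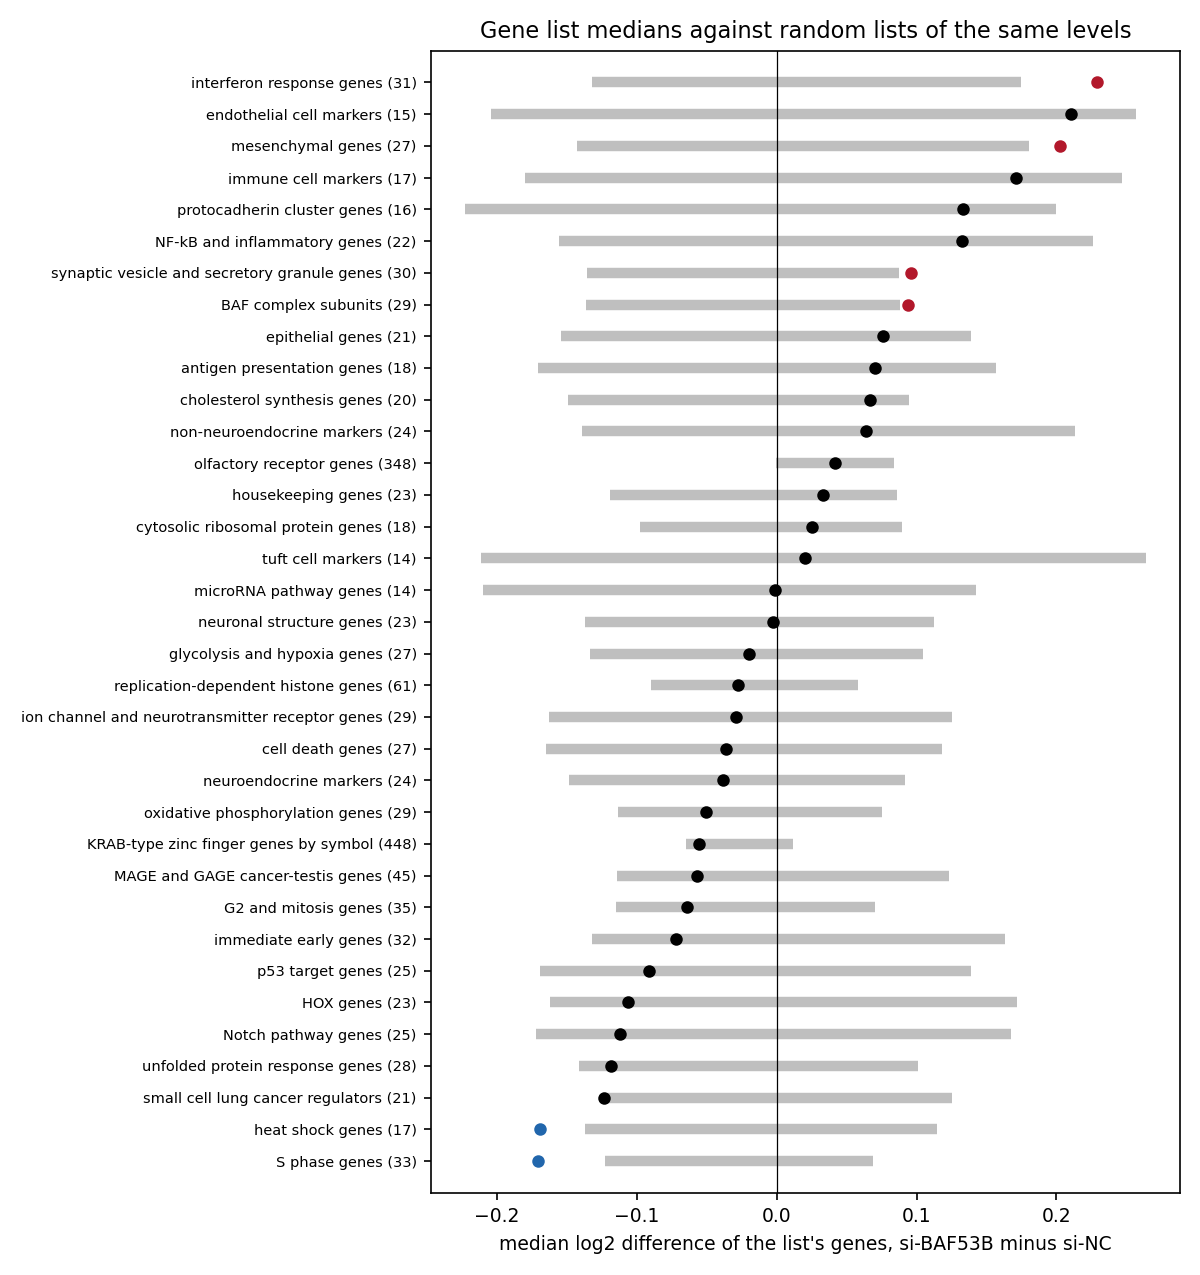
Median log2 difference, si-BAF53B minus si-NC, of each gene list reported here, with the number of measured genes in parentheses. Grey bars span the medians of 10000 random lists of the same size and levels between the lower and upper percentile limits; red dots lie above and blue dots below their bar, with S phase genes lowest at -0.17.

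Heat shock genes, which encode cytosolic and mitochondrial chaperones and the regulator HSF1, were lower in 14 of 17 cases, with a median of -0.17 at percentile 0.82. DNAJA1 (-0.65), FKBP4 (-0.55), CHORDC1 (-0.48) and HSPE1 (-0.29) were the furthest apart among members at or above the floor. Below it, the co-chaperone gene BAG3, chosen after its value was seen, was at 0.73. Against unmatched random lists the percentile was 4.43. Unfolded protein response genes had a median of -0.12 (percentile 5.80), with PDIA4 at -0.72, CHAC1 at -0.67, DDIT4 at -0.54 and the serine synthesis gene PSAT1 at 1.08. Immediate early genes had a median of -0.07 (percentile 13.4), with IER2 at -0.53.

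Interferon response genes had a median of 0.23 at percentile 99.5, with 19 of 31 higher. Only 6 members reached the floor, and these had a median of -0.05 at percentile 45.2; IFI6 was at 1.18 and RIGI at 0.23, whereas IFIT5 was at -0.43 and EIF2AK2 at -0.35. By the mean the list no longer stood apart (percentile 93.6). Markers of cell types that the culture should lack were also above 0: immune cell markers had a median of 0.17 (percentile 89.6; CD14 at 1.12, CD3E at 1.13, MS4A1 at -0.98), and endothelial cell markers had a median of 0.21 (percentile 93.9; ESAM at 1.44, ERG at -0.71). Of those markers, 0 of 17 immune and 2 of 15 endothelial genes reached the floor. Antigen presentation genes (median 0.07, percentile 84.1; HLA-C at 0.46) and NF-kB genes (0.13, percentile 83.7; RELB at 1.27 and IL6 at -1.44, both below the floor) did not stand apart.

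Mesenchymal genes had a median of 0.20 at percentile 98.6, with 18 of 27 higher and 7 at or above the floor. COL5A1 (0.60), TIMP1 (0.60), SNAI2 (0.39) and COL1A2 (0.38), genes of extracellular matrix, a protease inhibitor and a transcription factor, led those at or above it. The list was inside the limits by the mean (percentile 97.0), after removal of a trend on level (96.7) and after a second quantile normalization (96.9). Among the 7 members at or above the floor the median was 0.38, at percentile 99.8. Epithelial genes had a median of 0.08 (percentile 87.9), with KRT19 at 0.50 and the junction gene TJP1 at -0.55. Their members at or above the floor had a median of -0.09 (percentile 21.7).

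**Figure D3:**
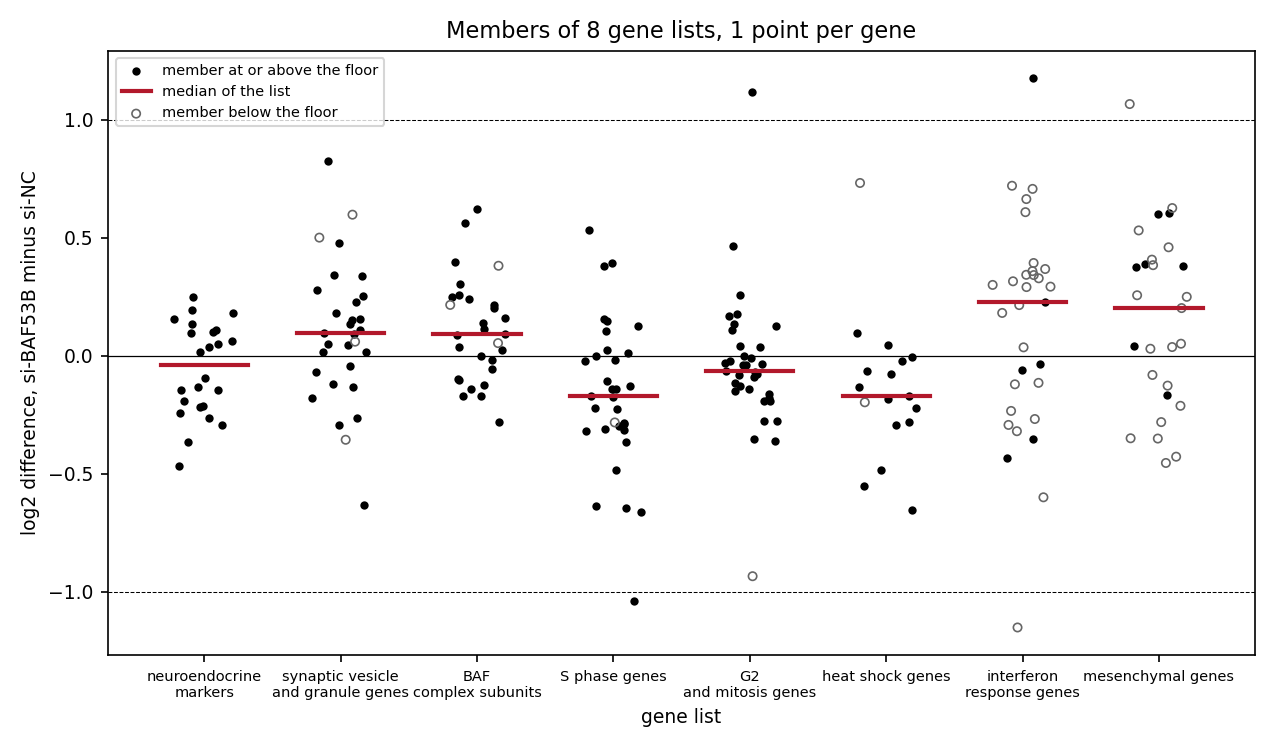
Log2 difference, si-BAF53B minus si-NC, of the genes of 8 lists, each point a gene, filled at or above the floor and open below it, with the list median as a red line. Among interferon response genes only 6 points are filled, and among S phase genes 24 of 33 lie below 0.

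Metabolic lists did not stand apart. Cholesterol synthesis genes had a median of 0.07 (percentile 93.7), with MVD at 0.53 and STARD4 at -0.40 beside SC5D. Glycolysis and hypoxia genes had a median of -0.02 (percentile 46.2), with PGAM1 at 0.96 and ADM at -0.70. Oxidative phosphorylation genes had a median of -0.05 (percentile 25.4), with NDUFS7 at -1.12. Ribosomal protein genes (0.03, percentile 72.4; RPS14 at 0.46) and housekeeping genes (0.03, percentile 83.9; GUSB at -0.72) stayed close to 0. MicroRNA pathway genes, whose products process or use small RNAs, had a median of 0.00 (percentile 65.8), with DICER1 2.01-fold higher and PRKRA at -0.59.

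Large families defined by symbol did not stand apart in the primary analysis. HOX genes had a median of -0.11 (percentile 10.6), with HOXB9 at -0.98. Zinc finger genes by symbol (ZNF and digits) had a median of -0.06 over 448 genes (percentile 6.42), with ZNF664 at -0.88. The list is labelled KRAB-type, but its members were not checked for a KRAB domain. The zinc finger list was below the lower limit in 4 of 9 alternatives, at percentiles of 0.05 by the mean, 0.31 against unmatched lists and 1.09 after removal of a trend on level among them. Cancer-testis genes had a median of -0.06 (percentile 16.4), with MAGEA3 at -0.56. Olfactory receptor genes, which a lung cancer line should hardly express, had a median of 0.04 over 348 genes (percentile 53.4), with OR2T2 at 0.69. In all, 6 of the 36 lists stood apart, 4 higher and 2 lower. Chance alone would give 1.8 on average if the genes within a list differed independently, which was not tested. In an unplanned comparison made in the same way, the genes of 4 of 23 chromosomes also fell outside the limits. The number of lists standing apart is therefore no measure of how many lists changed.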

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

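Apart from the ranking of the ACTL6B drop and the distributions of the arrays, probe sets without a gene name entered no comparison above. Of the 1266 at or above the floor, 4 were at least 2-fold higher in si-BAF53B than in si-NC and 6 at least 2-fold lower. Of all unnamed probe sets, TC0400010078.hg.1 had the largest positive difference, 2.99, from 3.26 in si-NC to 6.25 in si-BAF53B, with a mean below the floor. The lowest at or above the floor was TC0200013106.hg.1, at -1.65.

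Dim named genes also gave many 2-fold differences, 186 below the floor against 58 at or above it. Noise of dim probe sets is a candidate explanation, and a test set before its result was seen used olfactory receptor genes. Of 342 dim receptor genes, 6 (1.75%) differed by 2-fold or more, at percentile 55.78 of random lists of dim genes with the same levels, which spanned 0.585% to 3.22%. Genes that these cells should hardly express thus passed 2-fold at a share inside the range of dim genes of the same levels. The random lists were drawn from a pool that included the receptor genes, and the share among the other dim genes was 2.12%. Receptor genes had a median level of 3.25, so the comparison says little about dim genes closer to the floor. It does not show that any given dim gene, or the probe set at 2.99, differs by noise alone.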

How the results depend on the processing

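The gene span trend, the 50 level bins and the second quantile normalization of ACTL6B were chosen after the data were seen. ACTL6B stayed between -2.59 and -2.55 under 5 alternatives. The number of genes higher was 151 without a floor, 7 with a floor at the 75th percentile, 227 at 1.5-fold and 0 at 3-fold; the number lower was 93, 4, 343 and 3. These follow from the thresholds. Both counts kept within 1.5 times the reported ones under the other alternatives, and 51 of the 58 genes were shared after a lowess trend on level was removed and 52 after a second quantile normalization. S phase genes stayed below the lower limit in 9 of 9 alternatives (percentiles 0.22 to 0.73), and neuroendocrine markers stayed inside the limits in 9 of 9. BAF subunits kept their side in 6 of 9, with medians of 0.0906 among members at or above the floor and 0.0938 against unmatched lists and with 50 bins in the exceptions. Synaptic and granule genes missed the limit at 0.0959 against unmatched lists and at 0.0843 without shared members. Heat shock genes missed it only against unmatched lists (-0.17). Interferon genes lost their higher median among members at or above the floor, which leaves 6 genes, and missed the limit by the mean (0.13). The median of those 6, -0.0477 at percentile 45.2, changed sign but lay near that of all genes at or above the floor, -0.0356. Mesenchymal genes missed it by the mean (0.16), after the lowess trend on level (0.15) and after quantile normalization (0.15). The number of lists standing lower was 5 by the mean, 4 after the lowess trend and 5 after quantile normalization, against 2 reported. Of 256 values of the other 29 lists, 17 over 8 lists passed a limit that the reported value did not, 6 higher and 11 lower. The lower ones were small cell lung cancer regulators (5 of 9 alternatives), zinc finger genes by symbol (4 of 9), immediate early genes (by the mean) and Notch pathway genes (after quantile normalization). The higher ones were protocadherin and olfactory receptor genes, cholesterol synthesis genes and endothelial markers. Except where stated, the cause was not tested. Among members at or above the floor, 5 lists had fewer than 4 genes and gave no value. Signal near background limits what can be said of genes below the floor.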

Other observations

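The tests of cycling cells, of a shift shared with absent cell types and of the metallothionein family were chosen after the results they bear on were seen. Metallothionein genes, which bind metals and were singled out after their values were seen, gave a pair at 2-fold or more, MT1X (1.20) and MT1G (1.09). Of the others, MT1B at 0.53 and MT2A at 0.49 had means at or above the floor, while MT3 at -0.65 and MT1F at -0.37 lay below it. The hypothesis that the family as a whole is higher was tested on the 9 other measured members: their median was -0.09 at percentile 28.14, with 4 higher. That is inside the random spread. Only 2 of the 9, MT1B and MT2A, reached the floor, and both were higher. The test therefore leaves the hypothesis open, although a median of 0 or less had been stated as the bound against it. Related members may share probe sequence, which was not tested.

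The lower S phase genes are a pattern that a level-dependent trend left by the normalization might produce. After removal of that trend the list still had a median of -0.14, at percentile 0.3. The random lists were matched on level from the start, so this percentile adds little to the reported one. Without the 4 members of largest difference, all of them lower, the median of the other 29 was -0.14, at percentile 1.545. The lower median thus does not rest on those 4, but a median is little affected by a few extreme members in any case. Fewer cycling cells in the si-BAF53B culture stay open, since the S phase median minus the G2 and mitosis median was -0.11, at percentile 5.92 of random pairs of lists, which neither separates the lists nor shows both lower. With 1 culture per condition, a difference in growth between the cultures, an off-target effect of the siRNA and an effect of the ACTL6B knockdown are all untested. A lower S phase programme after the knockdown is therefore a hypothesis only. The 61 replication-dependent histone genes did not stand apart (median -0.03, percentile 37.5), and they were not tested against the S phase list.

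The higher interferon response genes stood at percentile 99.83, with a median of 0.24, after removal of a trend on level. Because the random lists were matched on level from the start, this percentile too adds little to the reported one. A shift shared with dim genes of absent cell types stays open: the 32 immune and endothelial markers together had a median of 0.20 (percentile 98.3), and the interferon median exceeded theirs by 0.03, inside the random spread (percentile 65.42 of random pairs). These markers were pooled after their lists, neither of which stood apart alone (89.6 and 93.9), had been seen, and other dim lists lay near 0, with olfactory receptor genes at 0.04 (53.4), tuft cell markers at 0.02 (46.8) and non-neuroendocrine markers at 0.06 (61.1). Induction of interferon genes stays open: the 6 members at or above the floor had a median of -0.05 at percentile 45.19. The bound set beforehand against induction was a median of 0 or less, which these genes met by less than the random spread; that bound was too loose for 6 genes, so after the values were seen neither it nor the metallothionein bound was taken to decide.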
